A study of Mus musculus with 3 samples.

How the data were processed

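Spleen B cells of female BXD2 mice treated with R848 or IL-4+R848 were isolated by negative selection, stained with hashtag and surface antibodies and sequenced as 3 single-cell 5' libraries, per the labels' protocols. The deposited files hold raw UMI counts per feature and barcode for genes and for 14 antibody tags (2 hashtags and 12 surface antibodies), with no normalization recorded. Counts were made with Cell Ranger 6.0.1, per the file headers, on mm10, per the submitters' processing notes, which also name Seurat 4.1.3 without its role. The files hold barcodes already chosen as cells, and barcodes with both hashtags had not been removed.

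The labels describe each library as a mixture of the 2 treatments, and the design written before the data were examined planned a treatment comparison only if the files named the treatment of each hashtag. The feature names did so (Con_fb for the control and IL4tr_fb for IL-4), and treatment was taken from these names alone. A cell was assigned when one hashtag had at least 64 UMIs and was at least 4-fold the other plus 1, a rule made after the hashtag counts were seen, because a standard demultiplexing rule set unsuitable thresholds on them. No expression was compared before. Barcodes with both tags were 10.7%, 8.25% and 9.20% of all barcodes in sets 1 to 3 (1559, 940 and 1309) and were removed, as were 475, 84 and 100 with too few tag UMIs. Scrublet scores at an expected rate of 0.06 marked 3, 2 and 0 cells, far fewer than the hashtags, so doublets of 2 cells of one treatment remain. Barcodes needed at least 500 genes and under 10% mitochondrial UMIs, which 587, 190 and 253 failed.

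Counts were scaled to 10000 per cell and logged, centred within sets, and clustered on 2000 variable genes, 30 principal components and 15 neighbours by Leiden at resolution 1 (seed 1). Test list, Ig variable, T cell receptor, mitochondrial and ribosomal protein genes were left out of clustering. Clusters were named by 17 marker lists fixed before the data were examined (follicular, marginal zone, transitional, germinal center, age-associated, plasmablast or plasma cell, B-1, cycling, early activated, T, NK, monocyte or macrophage, neutrophil, plasmacytoid and conventional dendritic, erythroid, and platelet or megakaryocyte cells). A cell type name needed at least 3 markers raised and the highest mean marker level among cell type lists. The early activated list named a cluster when its mean was above that of the best cell type list. The cycling list did so when its mean log2 level was above 2 and no cell type list reached 2. No name was given to clusters of low UMI counts or led by B cell precursor genes or another list's markers. These rules and exclusions, and that the age-associated name needs Itgax, were decided after the clusters were seen. Clustering was repeated without the 2021 genes called between treatments in any class, after the treatment was seen to split follicular-like cells into separate clusters. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

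UMI counts were summed per set, treatment and class (at least 79 cells per sum) and tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test) in R 4.3.3 with limma 3.58.1; genes were called at a Benjamini-Hochberg (BH) adjusted p under 0.05. CPM are on TMM-normalised library sizes. IL-4+R848 was compared with R848 within each class without a block, and classes were compared with follicular-like cells with the set as a block. Cells of a set share a library, so sets pair the 2 treatments, and the sums were checked for it on genes at a mean of at least 50 CPM. Deviations of the 2 follicular-like sums of a set correlated at 0.446, 0.380 and 0.367 (highest between sets -0.120), and of germinal center-like sums at 0.0642, 0.350 and 0.197 (0.0238). Those of plasmablast-like sums correlated at -0.0697, -0.0561 and -0.0442 (0.0826) and of the Zbtb32 cluster at 0.0671, 0.00432 and 0.00301 (0.135). Transitional-like (0.121, 0.114 and 0.133), activated-like (0.112, 0.167 and 0.0863) and marginal zone-like sums (0.135, 0.118 and 0.0889) lay between.

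A total of 16 gene lists fixed before the data were examined were tested with camera (log2 CPM with prior count 2, correlation 0.01, BH over lists), and with fry: IL-4 and STAT6 response, type I interferon, interferon gamma, TLR7 and NF-kB, MHC class II and costimulation, B cell receptor signalling, heavy chain constant genes, ER stress and secretion, DNA replication and mitosis, Myc targets and ribosome biogenesis, oxidative phosphorylation, glycolysis, trafficking receptors, cytokines and checkpoint genes, class switch and somatic mutation, and apoptosis and survival. Differences of the IL-4 effect between classes were tested as interactions in one edgeR fit. The genes named come from a rule fixed in advance: per comparison and list, up to 3 passing members with the largest change, the same direction in all 3 sets and at least 20 UMIs, plus the 5 largest rises and falls outside lists, markers and clustering genes, and Fcer2a, Il4ra, Tlr7, Irf7 and Ighg2c always; a list with no such member names its smallest p. Of these, the text prints a part, chosen after their values were seen, with a preference for genes whose call did not depend on 1 set.

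Shares were compared by exact two-sided permutation over the 6 sums, which cannot go below 0.10 with 3 against 3. Shares of cells with a UMI and co-detection of 12 pairs fixed in advance used cells thinned to 2000 UMIs. A fold against 0 counts was computed against 3 counts over the group, and ratios to 1 to 3 counts carry a 95% interval. Antibody gates were at 100 UMIs (also 50 and 200), with no correction for staining. Mixtures of 11 classes and unnamed clusters of at least 20 R848 cells in every set were fitted to the IL-4+R848 follicular-like profile by non-negative least squares over the genes called there, with weights summing to 1. Gene coordinates come from the GRCm38 annotation.

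In only 4 comparisons edgeR was tried on counts simulated with known changes and 1 dispersion for all genes, so real rates may differ. Camera, fry and interactions were not tried. In follicular-like treatment sums (11140 genes) 95.9% of 2-fold and 100% of 4-fold changes were found with 4.50% false among the calls; in marginal zone-like sums (8346 genes) 65.0%, 91.8% and 5.56%; in germinal center-like sums (9610 genes) 83.5%, 100% and 6.88%; and between germinal center-like and follicular-like cells (9638 genes) 97.0%, 100% and 3.43%. Alternatives fixed before the data were examined were DESeq2 1.42.0, no filter on low counts, the block and each set left out for the counts of genes called, between treatments and between classes. For class comparisons or shares of classes per set they were also DESeq2 size factors, only the 2 classes in the fit, resolutions 0.6 and 1.6, no centring, doublets kept, at least 200 genes with under 20% mitochondrial UMIs, and thinned cells; for lists between classes, estimated correlation, fry, no block and each set left out. Added after seeing the data were all other alternatives of treatment comparisons (among them size factors, resolutions, the looser filter and thinned cells), every alternative of treatment lists and of shares by treatment, hashtags 8-fold apart, removal of cells near barcodes with both tags, clusters without treatment genes, other ways of drawing the follicular-like class (without cluster 2, with transitional- and activated-like cells, or by an IgD gate at 100 UMIs), 1 treatment alone, co-detection within treatments, and the Zbtb32 cluster comparisons.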

Results

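Single-cell RNA libraries were made from spleen B cells of female BXD2 mice, a recombinant inbred strain that develops lupus-like autoimmunity with age. All animals received R848, a small-molecule agonist of the RNA sensor TLR7, at 40 µg per 20 g of body weight. It followed by 2 hours either a long-acting complex of 5 µg of IL-4 with 25 µg of an anti-IL-4 antibody (IL-4+R848) or 25 µg of the antibody alone (R848). Dosing was repeated after 2 days, spleens were taken 2 days later, and the series describes 3 mice per treatment. Cells of both treatments carried different hashtag antibodies and were pooled into 3 libraries (sets 1 to 3), and the hashtag names gave each cell its treatment. The question named by the series is how IL-4 changes TLR7-driven B cell development.

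Sets 1, 2 and 3 held 14519, 11389 and 14222 barcodes with 107244246, 96866964 and 99522280 gene UMIs, medians of 5480, 6580 and 4957 UMIs and of 1771, 1991 and 1626 genes per barcode. After filtering, 7152, 5642 and 7533 R848 cells and 5124, 4580 and 5081 IL-4+R848 cells remained. The IL-4+R848 cells were deeper, with medians of 6207, 6994.5 and 5199 UMIs against 5094, 5931 and 4447 in R848 cells. The labels do not say whether each set holds 1 mouse per treatment, so p-values measure only the spread between these sets, which may be technical. Levels below are means ± SD over the 3 sets in edgeR CPM units. A value after ± beside a log2 fold change is its standard error (SE). Every gene that the naming rule gave as rising or falling did so in all 3 sets. Counts of genes that rose or fell used only the adjusted p and the sign of the fitted change.

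Clustering gave 21 clusters, and follicular-like cells, named for Ighd, Ccr7 and related markers, made up 56.0 ± 1.6% of the cells of a set. Plasmablast-like cells made up 7.31 ± 1.11%, transitional-like cells 8.13 ± 1.30%, activated-like cells 5.20 ± 0.604%, marginal zone-like cells 4.8 ± 0.875% and germinal center-like cells 4.67 ± 1.05%. Smaller classes were cycling-like cells at 2.17 ± 0.149% and NK cell-like cells at 0.553 ± 0.275%, which passed the negative selection. A further cluster at 4.604 ± 0.929% raised 6 of the 7 age-associated B cell markers, led by Zbtb32, but not Itgax, and is called the Zbtb32 cluster. The requirement of Itgax was set after its markers were seen, and no age-associated contrast was made. The other marker lists, B-1 and T cell among them, named no cluster. Clusters that failed a naming rule, among them a pair led by B cell precursor genes, held 6.57 ± 1.97% of cells.

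On RNA clusters, follicular-like cells took a larger share of the cells with IL-4, and marginal zone-like, germinal center-like and plasmablast-like cells a smaller one. So that genes called between treatments did not draw the classes, shares were compared on clusters made without the 2021 of them. Follicular-like cells went from 45.2 ± 2.08% with R848 to 57.2 ± 0.279% with IL-4+R848. Marginal zone-like cells went from 6.35 ± 1.42% to 2.53 ± 0.634%, with ratios of 0.2498, 0.561 and 0.447 in the 3 sets. Germinal center-like cells went from 5.98 ± 1.55% to 2.69 ± 0.780% (ratios 0.517, 0.321 and 0.549), and plasmablast-like cells from 8.95 ± 1.41% to 4.97 ± 2.03% (0.891, 0.440 and 0.383).

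Every set showed the same direction for these classes and for activated-like cells, which went from 8.50 ± 0.751% to 7.17 ± 0.453%. Each gave an exact two-sided permutation p = 0.10, the lowest that 3 sets against 3 allow, so none could pass 0.05. Transitional-like cells stood at 13.5 ± 0.938% and 13.0 ± 1.99% (exact permutation p = 0.90; 2364 of them were follicular-like on clusters from all genes) and the Zbtb32 cluster at 2.89 ± 0.143% and 2.94 ± 0.851% (exact permutation p = 1.0). With clusters made from all genes, transitional-like cells were at 11.2% and 3.92%, activated-like cells at 7.49% and 2.09%, and the Zbtb32 cluster at 4.51% and 4.73%.

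**Figure D1:**
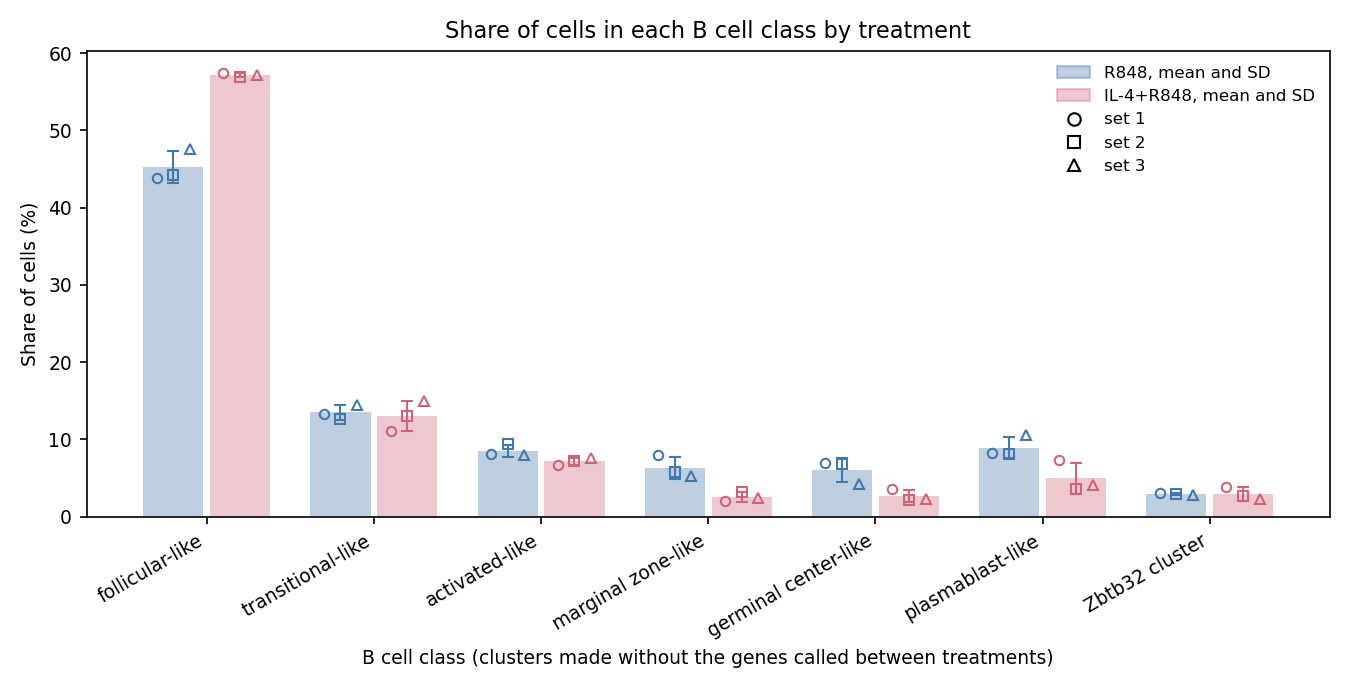
Share of cells (%) in each B cell class for R848 (blue) and IL-4+R848 (red), on clusters made without the genes called between treatments; bars are means over 3 sets, whiskers SD and symbols single sets. Follicular-like cells are at 45.2% and 57.2%, marginal zone-like cells at 6.35% and 2.53%, and germinal center-like cells at 5.98% and 2.69%.

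In follicular-like cells, IL-4+R848 was set against R848 to ask what IL-4 changes in the largest B cell class under TLR7 stimulation. Single IL-4 targets such as Nfil3 and Il4i1 rose strongly, MHC class II genes rose together, and more cytokine and checkpoint genes fell than rose. Nfil3, a transcription factor induced by IL-4, went from 3.59 ± 0.622 to 94.6 ± 13.9 CPM, and Il4i1, a secreted amino acid oxidase, from 75.4 ± 11.2 to 414 ± 22.8 CPM. H2-DMa, a chain of the peptide editor that loads MHC class II, rose from 585 ± 17.99 to 921 ± 19.3 CPM, and Apoe, the lipid carrier, fell from 436 ± 16.5 to 67.98 ± 20.3 CPM. Of 11271 genes tested, 993 rose and 937 fell at a Benjamini-Hochberg (BH) adjusted p under 0.05 in edgeR's quasi-likelihood test.

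The set was treated as a replicate only; with the set as a block 1417 genes rose and 1335 fell. Without set 1, 1222 genes passed in all, and without set 2, 834. Most R848 cells of this class lay in clusters 0 and 3 and most IL-4+R848 cells in clusters 1, 2 and 5, where they were 90.8%, 99.4% and 95.7% of the cells, so the class holds different clusters in the 2 treatments.

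Of the IL-4 and STAT6 response list, 5 rose and 3 fell of 12 tested members (6 and 4 adjusted over the list alone; camera BH-adjusted p = 0.08695). In cells gated by the IgD antibody (the IgD gate) the list passed, upward (camera BH-adjusted p = 0.0298, adjusted p = 0.232 with an estimated correlation). Nfil3 rose by a log2 fold change of 4.72 ± 0.14 (edgeR BH-adjusted p = 3.6e-08). Cish, an inhibitor of cytokine receptor signalling, rose by 4.15 ± 0.53 and Il4i1 by 2.46 ± 0.10 (edgeR BH-adjusted p at most 4.5e-04). Il4ra, the IL-4 receptor chain, rose from 60.1 ± 3.55 to 91.1 ± 2.92 CPM (edgeR BH-adjusted p = 7.9e-05). Fcer2a, which encodes CD23, was at 249 ± 39.2 and 294 ± 13.2 CPM and did not pass (log2 fold change 0.24 ± 0.10, edgeR BH-adjusted p = 0.118). It passed with the set as a block (0.25, edgeR BH-adjusted p = 0.0346) and without set 1 (0.39, edgeR BH-adjusted p = 0.0221). It also passed with no filter on low counts, with transitional- and activated-like cells added and in the IgD gate (edgeR BH-adjusted p = 0.0206, 0.0227 and 0.0142).

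Of the MHC class II and costimulation list, 11 rose and 1 fell of 13 tested members (11 and 1 adjusted over the list alone). H2-DMa rose by 0.65 ± 0.05 on the log2 scale (edgeR BH-adjusted p = 6.6e-06). Ciita, the master activator of class II transcription, rose by 0.63 ± 0.07 (edgeR BH-adjusted p = 1.5e-04) and H2-DMb2 by 0.56 ± 0.05 (edgeR BH-adjusted p = 4.4e-05). The list ranked above other genes (camera BH-adjusted p = 1.3e-06), but the call was lost at an adjusted p = 0.303 with an estimated correlation. Drawn in other ways, the class had 11 of 13 members raised without cluster 2. It had 12 of 14 raised with transitional- and activated-like cells added and 12 of 14 in the IgD gate.

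More cytokine, checkpoint and trafficking receptor genes fell than rose. Of 12 cytokine and checkpoint genes 0 rose and 7 fell (0 and 8 adjusted over the list alone; camera BH-adjusted p = 0.00646, adjusted p = 0.244 with an estimated correlation). Among them were Lta, a lymphotoxin chain, at -0.73 ± 0.13 and the checkpoint receptor gene Vsir at -1.06 ± 0.18 (edgeR BH-adjusted p at most 0.00393). Of 12 trafficking receptors 1 rose and 5 fell (1 and 5 adjusted over the list alone; camera BH-adjusted p = 0.0165, adjusted p = 0.303 with an estimated correlation). Ccr6, the CCL20 receptor, fell from 117 ± 6.84 to 59.6 ± 5.16 CPM and Cxcr4 from 41.7 ± 3.597 to 23.1 ± 6.45 CPM (edgeR BH-adjusted p at most 0.00607). Gpr183, an oxysterol receptor, rose from 59.2 ± 15.1 to 98.7 ± 6.696 CPM (edgeR BH-adjusted p = 0.007000). Lta missed the threshold without cluster 2 (-0.43, edgeR BH-adjusted p = 0.0684). In the IgD gate Vsir (-0.82) and Cxcr4 (-0.51) did not pass (edgeR BH-adjusted p = 0.0658 and 0.06501). There 0 cytokine genes rose and 3 fell. Without cluster 2, 1 and 3 did so, and neither list passed (camera BH-adjusted p = 0.1601 and 0.261). With transitional- and activated-like cells added 0 and 6 did so, and the trafficking list gave 0.0514 by the same test.

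Of the Myc target and ribosome biogenesis list, 15 rose and 0 fell of 18 members (16 and 0 adjusted over the list alone; camera BH-adjusted p = 3.1e-09, adjusted p = 0.244 with an estimated correlation). Srm, the spermidine synthase, rose from 28.5 ± 1.38 to 52.9 ± 1.895 CPM, and Dkc1 and Nhp2, parts of the pseudouridylation complex, by 0.47 ± 0.06 and 0.45 ± 0.05 on the log2 scale (edgeR BH-adjusted p at most 6.4e-04). This result depended on how the class was drawn: 2 members rose without cluster 2, 0 with transitional- and activated-like cells added and 0 in the IgD gate (camera BH-adjusted p = 0.0373, 0.719 and 0.519; adjusted p = 0.679 with an estimated correlation without cluster 2). In the IgD gate Srm stood at -0.06. On clusters made without treatment genes 9 rose and 1 fell.

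Receptor signalling and survival genes went both ways. In the B cell receptor list 3 rose and 5 fell of 18 (4 and 8 adjusted over the list alone; camera BH-adjusted p = 0.176). The inhibitory coreceptor gene Cd72 fell from 571 ± 60.7 to 359 ± 16.1 CPM and Pik3cd, a PI3 kinase subunit, by 0.64 on the log2 scale. Ms4a1, which encodes CD20, rose by 0.55 ± 0.07 (log2, edgeR BH-adjusted p at most 3.4e-04 for the 3). In the apoptosis and survival list 3 rose and 6 fell of 16 (3 and 8 adjusted over the list alone; camera BH-adjusted p = 0.153). Bcl2a1b and Bcl2a1d, near-identical copies of an anti-apoptotic gene whose reads can be split between them, fell, at -0.90 ± 0.08 and -0.86 ± 0.10 (log2; edgeR BH-adjusted p at most 1.6e-04). Of ER stress and secretion genes 5 rose and 2 fell of 19 (5 and 2 adjusted over the list alone; camera BH-adjusted p = 0.155, and 0.00693 without set 3). Xbp1, the unfolded protein response factor, rose from 55.4 ± 12.3 to 123 ± 3.86 CPM and Ell2, an elongation factor of antibody secretion, by 0.84 ± 0.07 (log2; edgeR BH-adjusted p at most 1.2e-04).

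Few interferon genes passed. Of the type I interferon list 1 rose and 3 fell of 27 (1 and 1 adjusted over the list alone; camera BH-adjusted p = 0.717), with a median log2 fold change of 0.02 and a mean of -0.07. In the IgD gate the list ranked upward (4 rose and 1 fell of 28; 7 and 1 adjusted over the list alone; camera BH-adjusted p = 0.0306, adjusted p = 0.727 with an estimated correlation). Irf7, a driver of interferon transcription, was at 15.6 ± 0.734 and 16.1 ± 0.813 CPM and did not pass (edgeR BH-adjusted p = 0.735), although it did in the IgD gate (0.46, edgeR BH-adjusted p = 0.00429) and with transitional- and activated-like cells added (0.30, 0.0213). In the interferon gamma list 1 rose and 2 fell of 14 (1 and 8 adjusted over the list alone; camera BH-adjusted p = 0.132, and 0.00164 without set 1). Gbp7, a guanylate-binding protein gene, fell by 0.73 ± 0.11 (log2, edgeR BH-adjusted p = 0.00148). It did not pass in the IgD gate (-0.48, edgeR BH-adjusted p = 0.06904) or with at least 200 genes and under 20% mitochondrial UMIs (-0.39, edgeR BH-adjusted p = 0.107). In the TLR7 and NF-kB list 2 rose and 2 fell of 20 (2 and 2 adjusted over the list alone; camera BH-adjusted p = 0.807). Bcl3, an atypical IkB gene, went from 120.4 ± 13.4 to 83.4 ± 3.35 CPM (edgeR BH-adjusted p = 0.00106). Tlr7 itself did not pass (-0.15 ± 0.10, log2; edgeR BH-adjusted p = 0.341).

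The other lists had few passing members. In oxidative phosphorylation 2 rose and 0 fell of 17 (2 and 0 adjusted over the list alone; camera BH-adjusted p = 0.08695), and in glycolysis 3 rose and 0 fell of 13 (4 and 0 adjusted over the list alone; 0.153). In DNA replication and mitosis 1 rose and 1 fell of 25 (0 and 1 adjusted over the list alone; camera BH-adjusted p = 0.639). The IgD gate, which admits cells of other classes, differed: there 0 rose and 19 fell of 28 (0 and 25 adjusted over the list alone), with a median log2 fold change of -0.66 (camera BH-adjusted p = 4.3e-12, adjusted p = 0.302 with an estimated correlation). In class switch and somatic mutation 1 rose and 0 fell of 12 (1 and 0 adjusted over the list alone; camera BH-adjusted p = 0.807). The class switch member was Apex1, a base excision repair endonuclease, at 47.8 ± 1.54 to 87.9 ± 4.81 CPM (edgeR BH-adjusted p = 6.2e-06). Among heavy chain constant genes 0 rose and 1 fell of 6 (0 and 1 adjusted over the list alone; camera BH-adjusted p = 0.8798). Ighg2b went from 74.8 ± 16.2 to 37.3 ± 2.197 CPM (edgeR BH-adjusted p = 3.9e-04). Ighg2c was at 22.7 ± 10.9 and 37.04 ± 34.9 CPM (edgeR BH-adjusted p = 0.446). The IgG subclass genes share sequence. In NK cell-like cells, which make no antibody, 12.03% of cells held a UMI of Ighg2c, so free RNA adds to these counts. Of 18 tested genes of cell handling stress, such as Fos and Jun, 13 fell and 1 rose, with set medians of -1.24, -0.96 and -0.41 on the log2 scale.

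Outside the lists, the largest rises were of genes close to absent in R848 cells. Cdh1, which encodes E-cadherin, was at least 36.3-fold higher and Klrg2 at least 35.6-fold higher, against a floor of 3 counts over the R848 group. Cbr3, a carbonyl reductase gene, was 302 times higher (95% counting interval 53.9 to 11950.0) and reached 6.83 ± 1.43 CPM. The largest falls were of Cpd, a carboxypeptidase gene, from 7.68 ± 1.37 to 0.8201 ± 0.213 CPM and of Apoe, at -2.68 ± 0.16 on the log2 scale (edgeR BH-adjusted p at most 6.6e-06). In the GRCm38 build, the protein-coding genes led with lie as follows: Nfil3 (ENSMUSG00000056749; chromosome 13, 52967209 to 52981073, minus strand), Il4i1 (ENSMUSG00000074141; chromosome 7, 44816387 to 44840809, plus strand), H2-DMa (ENSMUSG00000037649; chromosome 17, 34119541 to 34139101, plus strand) and Apoe (ENSMUSG00000002985; chromosome 7, 19696109 to 19699188, minus strand).

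**Figure D2:**
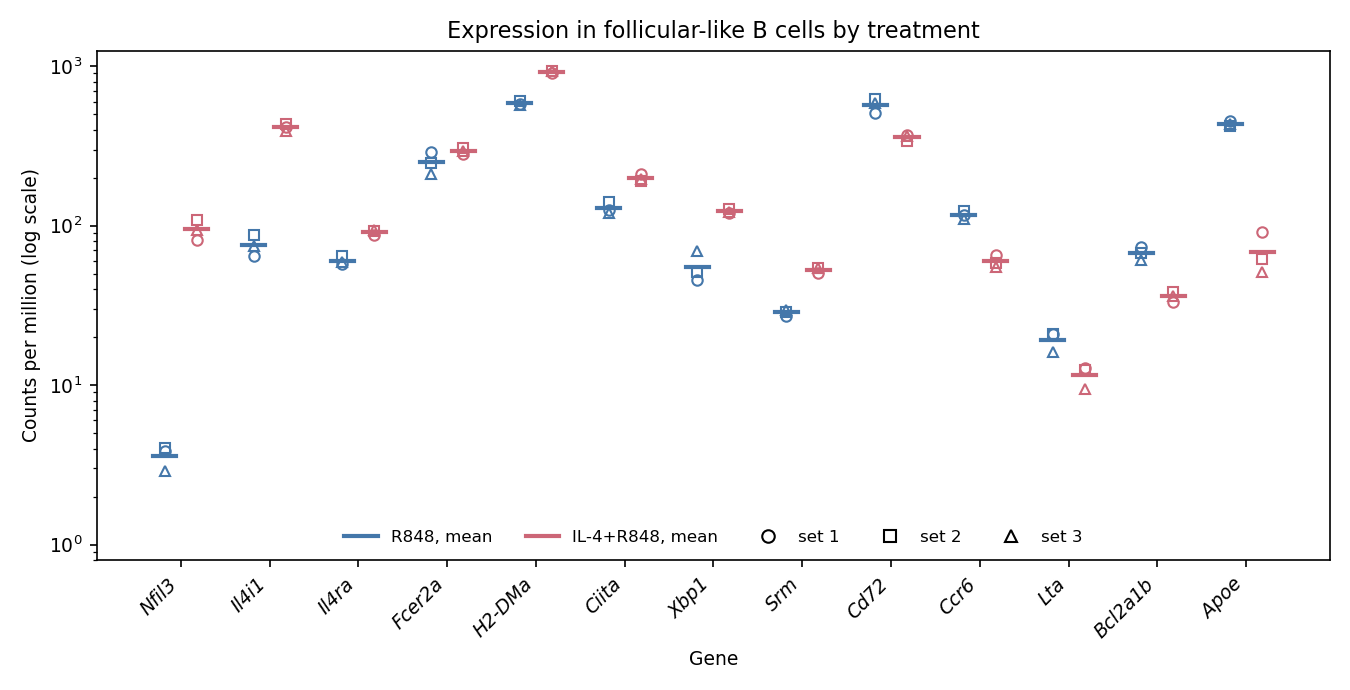
Expression (CPM, log axis) of 13 genes in follicular-like cells for R848 (blue) and IL-4+R848 (red), with a symbol per set and a line at the mean. Il4i1 lies at 75.4 and 414 CPM and Apoe at 436 and 68.0 CPM with no overlap between treatments, while Fcer2a, at 249 and 294 CPM, did not pass.

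**Figure D3:**
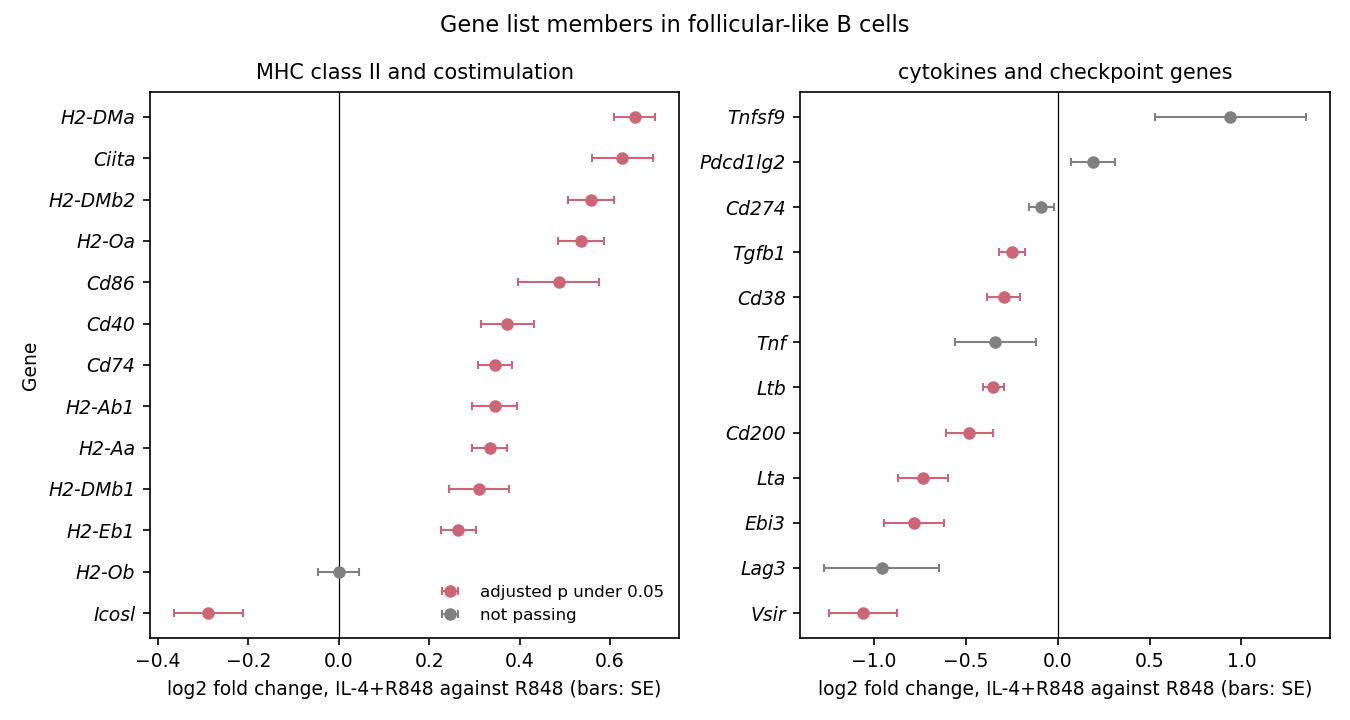
Log2 fold change, IL-4+R848 against R848, of the tested members of the MHC class II list (left) and the cytokine and checkpoint list (right) in follicular-like cells; points are fitted values, bars SE, red an adjusted p under 0.05. In the MHC class II list 11 of 13 members rose and 1 fell, and in the cytokine and checkpoint list 7 of 12 fell.

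Transitional-like and activated-like cells were compared in the same way, to ask whether immature and recently stimulated B cells carry IL-4 changes. In transitional-like cells Il4i1 rose from 66.5 ± 11.7 to 197 ± 29.3 CPM, Xbp1 from 85.5 ± 17.7 to 251 ± 40.8 CPM and Gpr183 from 16.5 ± 3.18 to 63.3 ± 21.6 CPM (edgeR BH-adjusted p at most 6.8e-04). Tmem123, a membrane protein gene, rose from 375 ± 7.86 to 1300.0 ± 33.1 CPM and Prelid2 from 39.2 ± 7.84 to 129 ± 35.6 CPM (edgeR BH-adjusted p at most 5.9e-04). Of 8187 genes 65 rose and 43 fell in edgeR's test; 88 and 76 did so with the set as a block, 71 in all without set 1 and 33 without set 2. The type I interferon list ranked upward (5 rose and 0 fell of 19 adjusted over the list alone, 0 over all genes; camera BH-adjusted p = 3.2e-04, adjusted p = 0.449 with an estimated correlation). So did the interferon gamma list (6 alone, 1 over all genes; camera BH-adjusted p = 0.00331, adjusted p = 0.446 with an estimated correlation).

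B cell receptor genes ranked downward in transitional-like cells (1 rose and 2 fell of 18; 1 and 6 adjusted over the list alone; camera BH-adjusted p = 0.01101, adjusted p = 0.446 with an estimated correlation). The call was lost without set 2 (0.1496) or 3 (0.0836). The ER list ranked upward (0.01101, adjusted p = 0.932 with an estimated correlation; 0.485 without set 2) and the cytokine list downward (0.01101, adjusted p = 0.446 with an estimated correlation; 0.163 without set 3) by the same test. These cells were few with IL-4, 577 against 2289. On clusters made without the genes called between treatments the transitional-like class gave 665 rises and 611 falls and shared 90 of the 108 calls. Of its 4686 cells, 2364 were follicular-like and 2212 transitional-like on clusters from all genes, so these values need not describe transitional-like cells. There 17 of 18 Myc target and ribosome genes rose (camera BH-adjusted p = 7.2e-12, adjusted p = 0.0774 with an estimated correlation).

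In activated-like cells, single IL-4 genes and most MHC class II genes rose as well. Nfil3 went from 7.56 ± 2.44 to 71.9 ± 13.1 CPM, Il4i1 from 298 ± 22.4 to 644 ± 92.97 CPM and H2-DMa from 431 ± 29.97 to 661 ± 11.98 CPM (edgeR BH-adjusted p at most 0.00133). H2-DMa did not pass in thinned cells (0.47, edgeR BH-adjusted p = 0.0608). In the MHC class II list 8 rose and 0 fell of 13 (9 and 0 adjusted over the list alone; camera BH-adjusted p = 2.9e-07, adjusted p = 0.208 with an estimated correlation). In the IL-4 list 2 rose and 0 fell of 11 (5 and 1 adjusted over the list alone; camera BH-adjusted p = 8.7e-04, adjusted p = 0.208 with an estimated correlation). In the type I interferon list 1 rose and 0 fell of 17 (3 and 0 adjusted over the list alone; camera BH-adjusted p = 1.3e-04, adjusted p = 0.537 with an estimated correlation). Of 8621 genes 59 rose and 25 fell in edgeR's test, and 36 in all passed without set 1. The ER list passed, upward, only without set 3 (camera BH-adjusted p = 0.0124). On clusters made without treatment genes 413 rose and 289 fell, and 70 of the 84 calls were shared, in a class of which 1386 cells were activated-like and 1161 follicular-like on clusters from all genes. There 7 of 23 type I interferon genes rose, but that class took in a cluster of 33 cells led by interferon genes, which were not tested apart and may carry the rise. There 3 of 18 Myc target genes fell (camera BH-adjusted p = 3.3e-04, adjusted p = 0.245 with an estimated correlation).

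In marginal zone-like cells single IL-4 genes and most MHC class II genes rose again. Nfil3 rose from 5.81 ± 2.07 to 56.5 ± 16.4 CPM, Il4i1 from 43.1 ± 4.53 to 106 ± 20.3 CPM and H2-DMa from 527 ± 15.2 to 805 ± 47.8 CPM. H2-Oa, a chain of the DM modulator DO, rose from 470.1 ± 11.8 to 712 ± 3.27 CPM (edgeR BH-adjusted p at most 3.9e-04 for the 4 genes). Cd79b, a signalling chain of the B cell receptor, rose by 0.41 ± 0.05 and Pxdc1 fell by 1.16 on the log2 scale (edgeR BH-adjusted p at most 9.3e-04). Pxdc1 did not pass in thinned cells (-1.18, edgeR BH-adjusted p = 0.123). Of the MHC class II list 9 rose and 0 fell of 13 (11 and 0 adjusted over the list alone; camera BH-adjusted p = 1.6e-12, adjusted p = 0.131 with an estimated correlation). Of the IL-4 list 3 rose and 0 fell of 10 (4 and 1 adjusted over the list alone; camera BH-adjusted p = 0.001100, adjusted p = 0.131 with an estimated correlation).

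The interferon gamma list ranked upward in marginal zone-like cells without a member past the test over all genes (3 and 0 adjusted over the list alone; camera BH-adjusted p = 0.0248, adjusted p = 0.339 with an estimated correlation). It did not pass without set 1 (0.366 by the same test). Tlr7 (-0.19 ± 0.27), Irf7 (-0.29 ± 0.38) and Fcer2a (0.07 ± 0.17, all log2) did not pass; their smallest edgeR BH-adjusted p = 0.884. Fcer2a passed on clusters made without treatment genes (0.58, edgeR BH-adjusted p = 0.04202). Of 8495 genes tested 64 rose and 27 fell in edgeR's test; without set 1, 58 passed in all and without set 2, 53. In simulations at 1 dispersion, 65.0% of 2-fold changes were found here and 95.9% in follicular-like cells.

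Germinal center-like cells changed in few genes. Tmem123 rose from 111 ± 7.99 to 257 ± 30.1 CPM (edgeR BH-adjusted p = 0.00144). Nfil3 went from 9.94 ± 1.02 to 27.6 ± 7.62 CPM and Gpr183 from 10.8 ± 2.26 to 30.7 ± 5.91 CPM (edgeR BH-adjusted p at most 0.0191). Nfil3 did not pass without set 1 (1.45, edgeR BH-adjusted p = 0.211) or set 2 (1.28, edgeR BH-adjusted p = 0.0857). Gpr183 did not pass without set 1 (1.59, edgeR BH-adjusted p = 0.121) or set 3 (1.34, edgeR BH-adjusted p = 0.117). With cells near barcodes with both tags removed, neither Nfil3 (1.30, edgeR BH-adjusted p = 0.168) nor Gpr183 (1.54, edgeR BH-adjusted p = 0.153) passed, and with hashtags 8-fold apart Gpr183 did not (1.02, edgeR BH-adjusted p = 0.2600). In thinned cells both missed the threshold (edgeR BH-adjusted p = 0.193 and 0.337). Of the MHC class II list 1 rose and 0 fell of 13 over all genes and 8 and 0 adjusted over the list alone (camera BH-adjusted p = 0.00109, adjusted p = 0.891 with an estimated correlation). The IL-4 list (1 rose and 0 fell of 11; 4 and 1 adjusted over the list alone) had a camera BH-adjusted p = 0.0724, or 0.0317 with the set as a block and 0.0247 without set 1.

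Myc target and glycolysis lists of germinal center-like cells passed downward by camera only without set 1 (BH-adjusted p = 0.0187 each), and the ER list upward only without set 3 (BH-adjusted p = 0.00807). Of 9739 genes 19 rose and 11 fell in edgeR's test, and 56 and 23 with the set as a block; 7, 12 and 17 passed in all without set 1, 2 and 3. The count was 4 without cells near barcodes with both tags, 11 with hashtags 8-fold apart, 10 in thinned cells and 84 by DESeq2. Il4ra (0.64 ± 0.12, log2) and Fcer2a (0.96 ± 0.30) were higher in level without passing (edgeR BH-adjusted p = 0.0646 and 0.325). Fcer2a passed with the block (edgeR BH-adjusted p = 0.0312) and with no filter on low counts (0.00185). Il4ra passed by DESeq2 (0.63, DESeq2 BH-adjusted p = 0.00866) and with no filter on low counts (0.62, edgeR BH-adjusted p = 0.00532).

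Plasmablast-like cells had no gene past the test. Il4i1 was at 6.11 ± 2.498 and 27.8 ± 12.2 CPM (edgeR BH-adjusted p = 0.347) and Ciita at 6.19 ± 0.325 and 13.3 ± 2.01 CPM (edgeR BH-adjusted p = 0.293). The IgA constant gene Igha was at 475 ± 102 and 1423 ± 353 CPM (edgeR BH-adjusted p = 0.293). DESeq2 called all 3 higher (DESeq2 BH-adjusted p = 0.00457, 0.00368 and 4.6e-06), and all 3 passed with no filter on low counts (edgeR BH-adjusted p = 0.0188 each). Ighg2c, a switched isotype gene, stood at 8445 ± 2975 and 7543 ± 1240.0 CPM. Of 9775 genes edgeR called 0, while 519 had an unadjusted p under 0.05, DESeq2 called 27 up and 11 down, and the block 1 and 1. Without set 1, 2 or 3 edgeR called 1, 2 and 1 genes. As sets, the MHC class II list (3 of 14 raised adjusted over the list alone; camera BH-adjusted p = 3.5e-08, adjusted p = 0.3103 with an estimated correlation) ranked upward. So did the IL-4 list (2 of 13 alone; camera BH-adjusted p = 1.4e-04, adjusted p = 0.228 with an estimated correlation). The Myc list did so too (0.00109, adjusted p = 0.582 with an estimated correlation) but not without set 1 (0.0736), and the interferon gamma list passed downward only without set 1 (0.00964) by the same test.

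In the Zbtb32 cluster, Nfil3 rose from 14.04 ± 5.33 to 107 ± 12.8 CPM, Tmem123 from 163 ± 5.38 to 674 ± 124 CPM and Zfp280b from 5.76 ± 0.915 to 28.1 ± 4.61 CPM (edgeR BH-adjusted p at most 0.00137). Apoe fell from 659 ± 98.3 to 317 ± 29.6 CPM (edgeR BH-adjusted p = 0.002199). Il4ra rose from 36.8 ± 4.06 to 70.02 ± 9.11 CPM (edgeR BH-adjusted p = 0.00877, and 0.116 without set 2 and 0.0987 in thinned cells). Ighg2c, the isotype gene tied to TLR7 and interferon responses, went from 309 ± 62.4 to 123 ± 54.2 CPM (edgeR BH-adjusted p = 0.03903). The call was lost without set 1 (edgeR BH-adjusted p = 0.09697) or set 2 (edgeR BH-adjusted p = 0.307) and on clusters made without treatment genes (edgeR BH-adjusted p = 0.0541). It was also lost without cells near barcodes with both tags, with hashtags 8-fold apart and in thinned cells (edgeR BH-adjusted p = 0.1496, 0.0898 and 0.117). Of 17 tested genes of cell handling stress 0 rose and 2 fell (Jun and Ier2, named after their values were seen), and the median log2 change of these 17 genes was -0.62, -0.90 and -0.12 in sets 1 to 3. Of 8672 genes 127 rose and 52 fell in edgeR's test; 38 passed in all without set 2 and 54 without set 3.

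Among lists in the Zbtb32 cluster, MHC class II (4 rose and 0 fell of 14; 7 and 1 adjusted over the list alone; camera BH-adjusted p = 5.6e-04, adjusted p = 0.401 with an estimated correlation) ranked upward. So did IL-4 (3 rose and 0 fell of 10; 5 and 1 adjusted over the list alone; 0.0301 and 0.233 by the same tests) and class switch genes (1 rose and 0 fell of 10; 1 and 0 adjusted over the list alone; 0.0314 and 0.233). Without set 1 their camera BH-adjusted p were 0.0527, 0.0622 and 0.0670. Myc target genes ranked upward with no member past the test over all genes (8 and 0 adjusted over the list alone; camera BH-adjusted p = 3.4e-06, adjusted p = 0.233 with an estimated correlation). B cell receptor genes (0 rose and 1 fell of 18; 2 and 7 adjusted over the list alone; 0.0194 and 0.233) and trafficking receptors (0 rose and 0 fell of 12; 0 and 2 adjusted over the list alone; 0.00634 and 0.277) ranked downward. Both lost the call without set 3 (0.0584 and 0.0697). The receptor list also lost it without set 1 (0.0622), and DNA replication genes passed downward only without set 2 (0.0324), by the same camera test.

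Comparisons between classes within sets asked which programs mark each B cell state, over the 9278 tested genes not used for clustering. The classes came from the same cells, so genes varying with clustering genes tend to pass and these tests are not independent. The sums pooled both treatments, whose parts differ between classes, so levels of genes that differ by treatment also carry this mix. Against follicular-like cells, germinal center-like cells raised division, mutation and energy genes. All 28 of 28 DNA replication and mitosis genes rose (camera BH-adjusted p = 1.3e-13). Ccna2, a cyclin gene, rose from 1.41 ± 0.984 to 200.1 ± 7.84 CPM and Rrm2, a ribonucleotide reductase subunit, from 1.42 ± 0.626 to 183 ± 4.82 CPM (edgeR BH-adjusted p at most 1.5e-15). Of class switch and mutation genes 11 rose and 1 fell of 12 (camera BH-adjusted p = 3.9e-04). Polh, polymerase eta, rose from 5.07 ± 0.124 to 45.8 ± 2.76 CPM and Ung, a uracil glycosylase, from 10.7 ± 0.212 to 63.7 ± 9.36 CPM (edgeR BH-adjusted p at most 1.5e-15). All 18 of 18 Myc target genes and all 17 of 17 oxidative phosphorylation genes rose. In glycolysis 11 rose and 2 fell of 14, with Ldha from 185 ± 7.24 to 799 ± 98.3 CPM (edgeR BH-adjusted p = 5.2e-15). These 3 lists gave camera BH-adjusted p = 2.3e-08, 2.3e-08 and 2.2e-04 (0.0777 each with an estimated correlation).

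Interferon, antigen presentation and sensing genes were lower in germinal center-like cells. Of type I interferon genes 0 rose and 21 fell of 25 (camera BH-adjusted p = 2.0e-05), with Rtp4 falling from 6.04 ± 0.642 to 0.305 ± 0.204 CPM (edgeR BH-adjusted p = 1.0e-10). Irf7 did not pass (0.07 ± 0.09, log2; edgeR BH-adjusted p = 0.473), but did with doublets kept (0.31, edgeR BH-adjusted p = 0.00348). In the TLR7 list 1 rose and 17 fell of 20, Tlr7 going from 13.5 ± 1.03 to 1.400 ± 0.244 CPM. In MHC class II 2 rose and 12 fell of 14, H2-Oa going from 615 ± 19.5 to 144 ± 13.1 CPM. In B cell receptor signalling 1 rose and 15 fell of 18, Cd22 going from 165 ± 7.59 to 54.4 ± 1.08 CPM (edgeR BH-adjusted p at most 4.3e-13 for the 3 genes). The TLR7, MHC class II and receptor lists gave camera BH-adjusted p = 1.4e-04, 1.1e-05 and 2.7e-05 (0.0777 each with an estimated correlation). DNA replication, class switch and type I interferon lists kept their calls at adjusted p = 0.00768, 0.0129 and 0.0422 with an estimated correlation.

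Also in germinal center-like cells, trafficking (3 rose and 8 fell of 12; camera BH-adjusted p = 0.0114, adjusted p = 0.0777 with an estimated correlation) and interferon gamma genes (2 rose and 12 fell of 14; 0.0112 and 0.1595) ranked downward. So did IL-4 response genes (4 rose and 9 fell of 13; 0.02299 and 0.118, and 0.1303 in R848 cells alone), while ER genes ranked upward (13 rose and 3 fell of 19; 0.0112 and 0.3504). Fcer2a fell from 269.7 ± 17.3 to 68.4 ± 21.9 CPM and the migration receptor genes Ccr6 and S1pr1 by 3.83 and 3.14 on the log2 scale. Bcl2, a survival gene, fell from 69.3 ± 5.07 to 7.78 ± 0.457 CPM (edgeR BH-adjusted p at most 1.0e-10 for the 4 genes). Heavy chain (6 rose and 1 fell of 7), cytokine (4 rose and 8 fell of 13) and apoptosis genes (6 rose and 8 fell of 16) did not pass as lists (camera BH-adjusted p = 0.159, 0.0614 and 0.4305). In all 3825 genes rose and 3356 fell in edgeR's test. Adjusted over each list alone the counts were within 1 of those over all genes.

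Plasmablast-like cells against follicular-like cells carried the secretory program. All 19 of 19 ER stress and secretion genes rose (camera BH-adjusted p = 5.5e-15, adjusted p = 0.0621 with an estimated correlation). The chaperone gene Hsp90b1 rose from 260.1 ± 32.3 to 10105 ± 1349.8 CPM and Edem1, of ER degradation, from 33.9 ± 0.939 to 2318 ± 175 CPM (edgeR BH-adjusted p at most 3.8e-19). All 7 of 7 heavy chain genes rose, Ighg2c from 30.8 ± 24.5 to 15224 ± 4698 CPM and Ighg1 from 14.1 ± 5.63 to 6785 ± 1145 CPM (edgeR BH-adjusted p at most 3.3e-09). The list gave a camera BH-adjusted p = 6.9e-05 (adjusted p = 0.01102 with an estimated correlation). Oxidative phosphorylation (16 rose and 0 fell of 17; 2.0e-06 and 0.105) and DNA replication genes (20 rose and 4 fell of 28; 0.00999 and 0.241) ranked upward by the same 2 tests. MHC class II (1 rose and 13 fell of 14; 2.6e-07 and 0.0797) and B cell receptor genes (2 rose and 14 fell of 18; 3.4e-05 and 0.105) ranked downward, as did TLR7 (2 rose and 15 fell of 20; 6.9e-05 and 0.105) and IL-4 genes (3 rose and 10 fell of 13; 0.00999 and 0.105).

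Ciita fell from 165 ± 6.97 to 15.01 ± 0.3704 CPM, Cd22 from 165 ± 7.59 to 13.7 ± 1.42 CPM and Il4ra from 76.2 ± 3.03 to 7.21 ± 0.474 CPM in plasmablast-like cells (edgeR BH-adjusted p at most 1.4e-17). Tlr9 fell from 23.1 ± 2.25 to 1.97 ± 0.281 CPM (edgeR BH-adjusted p = 7.7e-13), while Tlr7, at 13.5 ± 1.03 and 12.9 ± 1.07 CPM, did not pass (edgeR BH-adjusted p = 0.596). Irf7 rose from 15.6 ± 0.329 to 36.3 ± 2.71 CPM and the antiviral genes Isg20 and Bst2 by 4.96 ± 0.12 and 3.29 ± 0.09 on the log2 scale (edgeR BH-adjusted p at most 4.2e-11). The type I interferon list went both ways (7 rose and 15 fell of 25; camera BH-adjusted p = 0.456). So did the Myc (6 rose and 11 fell of 18), interferon gamma (7 rose and 3 fell of 14) and glycolysis lists (7 rose and 3 fell of 14), which did not pass. Nor did the trafficking (4 rose and 8 fell of 12), cytokine (5 rose and 7 fell of 13), class switch (6 rose and 4 fell of 12) and apoptosis lists (8 rose and 7 fell of 16). In all 3837 genes rose and 3374 fell in edgeR's test, and counts adjusted over each list alone were within 1 of those over all genes.

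With treatments pooled, marginal zone-like cells were lower than follicular-like cells in IL-4 response genes as a list, and higher in Il10 and Cd274. Of IL-4 response genes 0 rose and 6 fell of 13 (0 and 6 adjusted over the list alone; camera BH-adjusted p = 3.4e-04, adjusted p = 0.0897 with an estimated correlation). Il4i1 fell from 262 ± 27.2 to 52.1 ± 6.99 CPM and Fcer2a from 269.7 ± 17.3 to 71.3 ± 8.203 CPM (edgeR BH-adjusted p at most 4.3e-09). In the cytokine list 8 rose and 3 fell of 13 (8 and 3 adjusted over the list alone; camera BH-adjusted p = 0.181). Il10, an anti-inflammatory cytokine gene, rose from 0.107 ± 0.0261 to 4.46 ± 1.11 CPM, and Cd274, which encodes PD-L1, from 22.3 ± 0.598 to 76.4 ± 5.57 CPM (edgeR BH-adjusted p at most 9.8e-10). MHC class II genes ranked downward (2 rose and 10 fell of 14; 2 and 12 adjusted over the list alone; camera BH-adjusted p = 1.1e-04, adjusted p = 0.211 with an estimated correlation). Ciita fell from 165 ± 6.97 to 92.96 ± 4.405 CPM and the costimulatory gene Cd86 rose from 25.4 ± 2.02 to 52.8 ± 5.59 CPM (edgeR BH-adjusted p at most 2.3e-08). Tlr7 rose from 13.5 ± 1.03 to 23.3 ± 2.76 CPM and Irf7 fell from 15.6 ± 0.329 to 7.55 ± 1.05 CPM (edgeR BH-adjusted p at most 1.2e-05), but Tlr7 did not pass in IL-4+R848 cells alone (0.71, edgeR BH-adjusted p = 0.135).

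Among other lists in marginal zone-like cells, glycolysis ranked upward (5 rose and 0 fell of 14; 6 and 1 adjusted over the list alone; camera BH-adjusted p = 0.0269, adjusted p = 0.329 with an estimated correlation). This call was lost without the set as a block (0.0765) or without set 2 (0.0772). Trafficking genes (8 rose and 3 fell of 12; camera BH-adjusted p = 0.0595, and 0.0271 without set 3) went both ways. The integrin gene Itgb1 rose from 15.99 ± 0.941 to 48.8 ± 5.31 CPM, and S1pr4 fell from 109 ± 8.07 to 43.8 ± 5.05 CPM (edgeR BH-adjusted p at most 4.1e-09). Apoptosis genes (7 rose and 3 fell of 16) included Bcl2a1b at 1.42 ± 0.09 (log2, edgeR BH-adjusted p = 1.6e-10). Type I interferon (4 rose and 5 fell of 25), interferon gamma (6 rose and 2 fell of 14), TLR7 (6 rose and 4 fell of 20), B cell receptor (5 rose and 5 fell of 18) and heavy chain lists (2 rose and 0 fell of 7) did not pass. Nor did the ER (3 rose and 5 fell of 19), DNA replication (1 rose and 3 fell of 28), Myc (3 rose and 2 fell of 18), oxidative phosphorylation (0 rose and 6 fell of 17) and class switch lists (0 rose and 3 fell of 12). The Myc list passed, upward, in R848 cells alone (camera BH-adjusted p = 1.3e-04). Adjusted over each list alone the counts were within 2 of those over all genes. Of the genes not used for clustering, 1500 rose and 1350 fell in edgeR's test. Without set 1, 995 and 814 did so, and without set 2, 1025 and 850.

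The Zbtb32 cluster against follicular-like cells was higher in heavy chain constant genes as a list, and in single genes such as Cd80 and Itgb1. Of heavy chain genes 6 rose and 0 fell of 7 (6 and 1 adjusted over the list alone; camera BH-adjusted p = 2.1e-04, adjusted p = 0.0151 with an estimated correlation). Igha went from 10.1 ± 1.53 to 184 ± 40.4 CPM and Ighg2c from 30.8 ± 24.5 to 213 ± 54.96 CPM (edgeR BH-adjusted p at most 2.8e-05), but Ighg2c did not pass in IL-4+R848 cells alone (1.76, edgeR BH-adjusted p = 0.106). Cd80, a costimulatory ligand gene, rose from 0.421 ± 0.0814 to 23.1 ± 0.467 CPM and Itgb1 from 15.99 ± 0.941 to 78.4 ± 21.3 CPM (edgeR BH-adjusted p at most 1.1e-11). Vsir rose from 3.003 ± 0.413 to 20.4 ± 3.93 CPM, and Fcer2a fell from 269.7 ± 17.3 to 94.8 ± 27.01 CPM (edgeR BH-adjusted p at most 7.0e-08). Ranked upward by camera were glycolysis (10 rose and 0 fell of 14; BH-adjusted p = 1.3e-06, adjusted p = 0.0579 with an estimated correlation) and ER genes (14 rose and 1 fell of 19; 5.0e-06 and 0.198). So were oxidative phosphorylation (9 rose and 0 fell of 17; 4.5e-05 and 0.198) and DNA replication genes (11 rose and 1 fell of 28; 0.00488 and 0.198). The same tests ranked upward Myc (6 rose and 0 fell of 18; 0.0172 and 0.3803), trafficking (5 rose and 2 fell of 12; 0.0172 and 0.159) and apoptosis genes (8 rose and 3 fell of 16; 0.0231 and 0.1301).

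MHC class II (2 rose and 8 fell of 14; 0.00994 and 0.268) and B cell receptor genes (3 rose and 10 fell of 18; 0.0231 and 0.328) ranked downward in the Zbtb32 cluster by the same tests. The MHC class II list had a median log2 fold change of -0.23 and a mean of 0.16. In R848 cells alone the MHC class II, receptor and apoptosis lists did not pass (camera BH-adjusted p = 0.207, 0.171 and 0.152). Cytokine genes (7 rose and 2 fell of 13; camera BH-adjusted p = 0.105, and 0.0467 without set 3) did not pass, nor did the IL-4 (1 rose and 4 fell of 13), type I interferon (2 rose and 7 fell of 25), interferon gamma (4 rose and 1 fell of 14), TLR7 (1 rose and 5 fell of 20) and class switch lists (0 rose and 3 fell of 12). Adjusted over each list alone the counts were within 1. Of the genes not used for clustering, 1746 rose and 1319 fell in edgeR's test, 2009 and 1068 with DESeq2 size factors, and 1908 passed in all without set 1.

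Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs. Il4i1 was found in 12.3 ± 1.57% of follicular-like R848 cells and 44.1 ± 2.76% of IL-4+R848 cells (23.6% and 68.4% unthinned), against 0% and 1.72% of NK cell-like cells as background. Fcer2a was found in 36.7 ± 5.49% and 37.2 ± 0.947% of follicular-like cells (57.6% and 63.8% unthinned), against 0% and 1.67%. Median depths before thinning were 4422 and 5856 UMIs in follicular-like cells and 5821 and 7298 in NK cell-like cells, and 326 and 224 follicular-like cells and 2 and 4 NK cell-like cells were too shallow. Over both treatments Ighg2c was found in 32.6 ± 7.60% of plasmablast-like and 15.8 ± 2.05% of germinal center-like cells (44.96% and 44.1% unthinned), against 3.96 ± 3.08% of NK cell-like cells. Igha was in 21.6 ± 2.75% of the Zbtb32 cluster (33.6% unthinned), against 1.00%. Median depths of these 3 classes were 16596, 14064.5 and 5893 UMIs in R848 cells and 18013, 16321 and 7426.5 in IL-4+R848 cells.

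Co-detection of 12 gene pairs in 31440 thinned B cells asked whether IL-4 targets and TLR7-associated genes sit in the same cells. Pairs were counted over all classes together, so class differences in both genes can move these values. Il4i1 and Fcer2a were found together more often than independence gives, with a log2 odds ratio of 1.01 ± 0.05 (SD over 3 sets). So were Itgax and Tbx21 (4.63 ± 0.79, from 6 cells), Tbx21 and Cxcr3 (1.34 ± 0.48, from 33 cells) and Tlr7 and Ifit3 (2.14 ± 0.75, from 12 cells), each above 0 in every set. In strata of depth Itgax with Tbx21 fell to 2.76 and Tbx21 with Cxcr3 to 0.85, and with doublets kept the latter gave 0.64 ± 0.72. Fcer2a with Tbx21, the T-bet gene of age-associated B cells, gave -0.42 ± 0.54, with Itgax -0.40 ± 1.02, with Cr2 0.09 ± 0.14 and with Ifit3 -0.30 ± 0.29. Il4ra with Tbx21 gave 0.15 ± 0.35 and with Ifit3 -0.80 ± 0.69, Ighg2c with Tbx21 0.12 ± 0.52, and Tbx21 with Ifit3 0.02 ± 0.98, from 1 cell. In strata of depth 3 of these were above 0 in every set, Il4ra with Tbx21 (0.32 ± 0.13), Ighg2c with Tbx21 (0.50 ± 0.28) and Tbx21 with Ifit3 (0.91 ± 0.43). So was Fcer2a with Cr2 (0.34 ± 0.06), and Fcer2a with Ifit3 was below 0 in every set (-0.42 ± 0.08). With 3 sets an exact sign-flip test cannot go below 0.25, so none of these was tested against 0.05.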

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

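The tests of the GL7 gate and of the CD21 and CD23 gate were set before their results were seen; the tests of dilution, of clusters without called genes, of mixtures of classes, of thinning, of handling genes and of other splits, and the choice of antibodies, came after. Antibody levels and the interaction tests belong to no comparison of the report.

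In a direct interaction test against follicular-like cells, the fitted IL-4 effect differed between classes for some genes. On clusters without treatment genes, 267 genes passed in transitional-like, 509 in activated-like, 274 in marginal zone-like, 214 in germinal center-like and 47 in plasmablast-like cells and 14 in the Zbtb32 cluster (edgeR BH-adjusted p under 0.05). On clusters from all genes the counts were 259, 87, 351, 394, 84 and 61. Nfil3 rose less in germinal center-like cells (difference -3.01 ± 0.21, log2 ± SE) and in plasmablast-like cells (-3.57) than the 4.61 of follicular-like cells. The fall of Apoe was smaller by 1.92 ± 0.11 in germinal center-like cells and by 1.62 in the Zbtb32 cluster, Gpr183 rose more in transitional-like cells (1.91 ± 0.10), and the early response gene Junb fell less in marginal zone-like cells (1.10 ± 0.06). The examples were chosen after their values were seen.

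Surface antibodies showed signals outside the RNA comparisons. Cells of the 2 treatments were stained apart, and IL-4+R848 cells carried more UMIs of their own hashtag (medians 2236, 2155.5 and 1732 in sets 1 to 3, against 1398, 1312 and 1256 in R848 cells), so uncorrected antibody UMIs and gates compare stainings as well as cells. Follicular-like cells with IL-4 had median UMIs of 397 for CD23 (208 in the R848 group), 10.3 for GL7 (4.67) and 33.3 for IgM (12.3). GL7 high cells were 17.1 ± 2.83% of IL-4+R848 and 9.83 ± 2.85% of R848 cells, and CD273 (PD-L2) high cells 0.661% and 0.1303%.

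Marginal zone-like and germinal center-like cells were a lower share of the cells with IL-4 in every set. On clusters made without the genes called between treatments the highest ratio over sets was 0.561 for marginal zone-like and 0.549 for germinal center-like cells, which argues against clusters drawn by those genes as the cause; clusters drawn by further genes that respond to IL-4 are not excluded by it. A gate of CD21 high, CD23 low cells gave a ratio nearest to 1 of 0.251, but within follicular-like cells the CD21 median was lower with IL-4 (27.7 against 61.7 UMIs) and the CD23 median higher, so the gate itself may be moved by the treatment and decides nothing; the GL7 gate (1.55) is open in the same way. Cells high for GL7 and low for IgD, a gate chosen later, were 7.65% against 7.81% (ratios 0.9298, 0.877 and 1.246; exact permutation p = 1.0). These ratios lie in the range set for clusters drawn by responding genes, which stays open for germinal center-like cells, although staining may move this gate too. Dilution by more follicular-like cells could account for a part, since among cells outside the follicular-, transitional- and activated-like classes the highest ratio was 0.829. A loss of these cells under IL-4, or a change of their markers, remains open.

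The genes changed in follicular-like cells were weighed against a shift between classes, depth and handling. In the R848 class mixture nearest to the IL-4+R848 profile, 697 of 993 raised genes showed under 0.5 of their change in every set. So did 931 of 937 lowered genes. A shift between these classes is unlikely as the whole source. Thinned cells (1405 genes) keep their profile, so depth stays open. Follicular-like clusters formed 1 unit, so a shift among them stays open, as does one between classes for the other raised genes, Srm included. An IgD gate called 1485 genes but decides nothing, as 19 of 28 DNA replication genes fell and other classes may be unequal in it. Handling of the cells of each treatment before pooling cannot be told apart from treatment for stress genes such as Fos and Jun: in sets 1 to 3 their median change was 0.376, 0.258 and 0.538 of that in follicular-like cells in marginal zone-like cells, and 0.407, 0.0676 and 0.111 of it in germinal center-like cells. In the classes not named by that test it was 0.615, 0.123 and 0.988 in activated-like cells, 0.502, 0.944 and 0.286 in the Zbtb32 cluster, 0.320, -0.0147 and 0.451 in transitional-like cells, and 0.223, 0.207 and 0.0695 in plasmablast-like cells. The ratios ran from about 0 to near 1, classes can differ in their response to handling, and the 2 treatments were stained apart. Reads shared between near-identical genes touch Bcl2a1b and Bcl2a1d and the IgG genes, and free RNA is common to both treatments of a set. A response to IL-4 is a hypothesis that stays open.

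The 6 sums split into 3 and 3 in 10 ways, the real one among them, too few for a share under 0.05. Split by treatment, follicular-like cells gave 1930 genes (highest other split 0), transitional-like 108 (2), activated-like 84 (2), marginal zone-like 91 (1), germinal center-like 30 (1), plasmablast-like 0 (2) and the Zbtb32 cluster 179 (0); 3 of the other 9 splits also part every pair. As many genes came from 1 of the 10 splits in each class but plasmablast-like, where it was 10 of 10. Split by class, germinal center-like cells gave 7181 (0), plasmablast-like 7211 (0), marginal zone-like 2850 (0) and the Zbtb32 cluster 3065 (0).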

How the results depend on the processing

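Of 1738 values of named genes under alternatives, 1680 kept their direction and side of the threshold, 38 fell short of it, 19 newly passed it and 1 changed sign: Srm in follicular-like cells, at -0.0635 (log2; edgeR BH-adjusted p = 0.551) in the IgD gate against 0.89 in the class. Of the other values 375 stayed and 157 moved, none with a change of sign in a called value. Causes were not tested except where the setting itself tests fewer genes, sums or UMIs. Alternatives chosen after seeing the data are named with the methods. The alternatives kept 811 to 1929 of all 1930 treatment calls in follicular-like and 3 to 30 of 30 in germinal center-like cells.

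Counts of genes called by treatment moved by over 1.5 times as follows, against 108 in transitional-like, 84 in activated-like, 91 in marginal zone-like, 30 in germinal center-like, 0 in plasmablast-like cells and 179 in the Zbtb32 cluster. Without a filter on low counts they were 329, 356, 294, 196, 14 and 419. On clusters made without treatment genes they were 1276, 702 and 157 in the first 3 and 113 in the Zbtb32 cluster. With the set as a replicate block 164 passed in transitional-like, 79 in germinal center-like and 2 in plasmablast-like cells; beyond these, the counts of follicular-like cells, and Fcer2a and the IL-4 list as printed in the report, the block changed no call of a named gene or list. DESeq2 called 84 in germinal center-like and 38 in plasmablast-like cells. Thinned cells gave 29 in activated-like, 48 in marginal zone-like, 10 in germinal center-like and 1 in plasmablast-like cells. Hashtags 8-fold apart gave 11 and 2, and removal of cells near barcodes with both tags 4 and 4, in germinal center-like and plasmablast-like cells. Beside the 0 in plasmablast-like cells, 519 had an unadjusted p under 0.05.

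Leaving out each set in turn gave 834 to 1401 genes in follicular-like, 33 to 116 in transitional-like, 36 to 64 in activated-like, 53 to 61 in marginal zone-like, 7 to 17 in germinal center-like and 1 to 2 in plasmablast-like cells and 38 to 146 in the Zbtb32 cluster. The lowest came without set 2 in follicular-like and transitional-like cells and the Zbtb32 cluster, and without set 1 in activated-like and germinal center-like cells. Against follicular-like cells, marginal zone-like cells gave 1809 to 2164 and the Zbtb32 cluster 1908 to 2296, lowest without set 1. Lists past camera, with each set left out, were 3 to 5 in transitional-like cells (fewest without set 2 or 3), 1 to 4 in germinal center-like cells (fewest without set 2) and 2 to 7 in the Zbtb32 cluster (fewest without set 1).

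Between classes, thinned cells gave 4400 genes for germinal center-like, 4580 for plasmablast-like and 1369 for marginal zone-like cells and 1162 for the Zbtb32 cluster, and IL-4+R848 cells alone 792 for marginal zone-like cells and 1201 for the Zbtb32 cluster. With an estimated correlation, camera called 0 lists in every treatment comparison, 3 in germinal center-like, 1 in plasmablast-like and 0 in marginal zone-like cells and 1 in the Zbtb32 cluster. By fry, directional and mixed, the lists called were 8 and 14 in follicular-like, 0 and 9 in transitional-like, 5 and 7 in marginal zone-like and 0 and 5 in germinal center-like cells for treatment, 5 mixed in activated-like and 0 directional in plasmablast-like cells; between classes they were 13 and 16 in plasmablast-like, 8 and 15 in marginal zone-like cells and 16 and 16 in the Zbtb32 cluster. Camera called 2 lists in follicular-like cells without cluster 2 and 2 with transitional- and activated-like cells added, against 4; 5 in activated-like cells on clusters without treatment genes; and 2 in germinal center-like cells with the replicate block and on clusters without treatment genes.

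The share difference by treatment, in percentage points, depended on the clusters. With all genes, it was 23.6 in follicular-like, -7.28 in transitional-like and -5.40 in activated-like cells. In that order it was 23.0, -7.06 and -4.75 at resolution 0.6; 31.4, -7.68 and -12.9 at 1.6; 32.1, -7.37 and -13.8 without centring; 4.93, -7.27 and -3.73 with at least 200 genes and under 20% mitochondrial UMIs; 29.6, -6.95 and -5.03 with doublets kept; 22.1, -7.93 and -5.85 with hashtags 8-fold apart; and 23.8, -8.14 and -6.09 without cells near barcodes with both tags. Marginal zone-like cells moved to -11.3, -5.40 and -5.47 in the last 3 of these settings, and germinal center-like cells to -1.60 with hashtags 8-fold apart.

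Shares per set moved for follicular-like cells to 50.3% on clusters without treatment genes (54.0% at resolution 1.6), 49.5% at resolution 1.6, 48.8% without centring, 40.4% with at least 200 genes, 50.6% with doublets kept, 58.1% with hashtags 8-fold apart and 58.1% without cells near barcodes with both tags. Transitional-like cells moved to 13.3% and 10.3% and the Zbtb32 cluster to 2.91% and 2.55% (3.19% at resolution 1.6) on clusters without treatment genes at resolutions 1 and 0.6. Activated-like cells moved to 7.92%, 7.18% and 9.37% on those clusters at resolutions 1, 0.6 and 1.6, 11.4% at resolution 1.6, 12.7% without centring and 3.70% with at least 200 genes. Marginal zone-like cells moved to 9.52% with doublets kept and were not named with at least 200 genes. Germinal center-like cells moved to 3.46% with doublets kept, 3.41% with hashtags 8-fold apart and 3.31% without cells near barcodes with both tags, and plasmablast-like cells to 5.84% and 5.25% in the last pair of settings and 8.52% on clusters without treatment genes at resolution 0.6.

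Unthinned cells held Il4i1 in 23.6% and 68.4% and Fcer2a in 57.6% and 63.8% of follicular-like cells, Ighg2c in 44.96% of plasmablast-like and 44.1% of germinal center-like cells, and Igha in 33.6% of the Zbtb32 cluster; with doublets kept Il4i1 was in 15.05% of R848 cells. For co-detection, Fcer2a with Ifit3 moved to 0.15, Il4ra with Ifit3 to -0.0248 and Tbx21 with Cxcr3 to 0.64 with doublets kept. In strata of depth Il4ra with Ifit3 gave -0.0524, Tbx21 with Cxcr3 0.85, Itgax with Tbx21 2.76, Fcer2a with Cr2 0.34 and Il4i1 with Fcer2a 1.22. Without plasmablast-like and cycling-like cells Fcer2a with Cr2 gave -0.0785 and Il4i1 with Fcer2a 0.80, and within treatments the latter gave 0.93. No age-associated comparison or its alternatives were made.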

Other observations

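The test of light chains below was set before its result was seen, after the heavy chain gene had been noticed; the antibody gates were chosen after the feature list was seen, and compare cells stained apart. With IL-4, CD138 high cells, the surface mark of plasma cells, were 4.65% against 8.85% in the R848 group (set ratios 0.817, 0.403 and 0.362). CD21 high, CD23 low cells were 1.67% against 8.74% (0.127, 0.251 and 0.242). CD80 high cells were 2.65% against 2.36%, CD11c high cells 0.538% against 0.577%, CD95 high cells 1.12% against 1.26% and CD93 high cells 1.12% against 1.48%.

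Median CD23 antibody UMIs also differed in classes whose Fcer2a RNA did not pass: 265 with IL-4 against 52.7 in germinal center-like cells, and 227 against 51.7 in the Zbtb32 cluster. Median CD21 in marginal zone-like cells was 85.7 against 263. Cycling-like cells were 2.07% with IL-4 and 2.39% in the R848 group on clusters without treatment genes (exact permutation p = 0.30), and NK cell-like cells 0.827% and 0.396% (exact permutation p = 0.20).

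In set 2, the heavy chain variable gene Ighv9-2 led in 27 of 441 plasmablast-like R848 cells with a variable gene at 10 UMIs or more for both chains (6.12%) and in 17 of 263 germinal center-like ones (6.46%). Free RNA of 1 abundant transcript would pair it with light chains in the shares of other cells. Instead 19 of the 27 (70.4%, 95% interval 49.8% to 86.2%) used Igkv2-137, against 1.21% of other plasmablast-like cells, and 13 of the 17 (76.5%, 50.1% to 93.2%) used Igkv6-25, against 2.44%. Of 79 germinal center-like IL-4+R848 cells of set 2, Ighv9-2 led in 2, and both used Igkv6-25; a clone in both treatments or a wrong hashtag call was not told apart. In set 1, 6 of 8 such plasmablast-like R848 cells of 585 used Igkv2-137, against 1.73% of other cells. Free RNA of 1 abundant heavy chain transcript is therefore an unlikely source. Free RNA that carries both chains is not excluded by this test. Expanded clones are a hypothesis that these data do not test further, since no receptor sequences were used here.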
